A study of Mus musculus with 30 samples.

How the data were processed

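Polyadenylated RNA was sequenced from primary mouse cells of 2 kinds, thioglycollate-elicited macrophages and hepatocytes, each exposed in culture to 5 ligands of the liver X receptors (LXR) or related sterols and to vehicle. The design text gives 3 replicates per macrophage group and 2 per hepatocyte group, 30 libraries in 12 groups. It does not say whether replicates came from separate animals or separate cultures, so p-values measure only the spread between these samples, which may be technical in part. Libraries were built from dUTP-marked second strands and size selected at 223 to 375 bp.

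Per the submitters' processing notes, reads were aligned with STAR and counted with HOMER on the mouse genome build mm10, with no versions given. The deposited count tables hold raw counts of reads over the exons of 1 RefSeq transcript per gene, with replicates not pooled, per the file headers (HOMER's exon counting with genes condensed and no adjustment). The deposited RPKM tables hold the same genes scaled by transcript length and library total, per the file headers, under column names that say FPKM. The RPKM tables served only as a check: for genes over 500 counts they deviated from counts divided by length and by 1 total per library by at most 0.024% in macrophages and 0.023% in hepatocytes. The count and RPKM tables named another transcript for 2777 genes in macrophages and 3200 in hepatocytes. The headers state no strand option, so reads of overlapping genes on opposite strands may be counted together. There were 24063 genes in the macrophage table and 24453 in the hepatocyte table, with 23704 symbols in both. All columns mapped to a labelled sample.

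Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, libraries were scaled by TMM factors, and a quasi-likelihood model with 1 mean per group was fitted to the 6 groups of a cell type together. This left 11544 genes in macrophages and 13176 in hepatocytes, with 12 and 6 residual degrees of freedom and a common coefficient of biological variation of 0.0554 and 0.106. Each ligand was compared with vehicle, and 4 comparisons set ligands against each other (MePipHCA with DMHCA, DMHCA with T0901317, MePipHCA with T0901317, DMHCA with desmosterol). A further 5 comparisons tested whether a ligand's change over vehicle differed between the cell types, as an interaction in 1 fit of all 30 libraries with 13701 genes, 18 residual degrees of freedom and a coefficient of variation of 0.0771. For that fit the tables were joined by gene symbol. The plan had named the row identifier, but the tables list different transcripts for some genes. Cell type is confounded with culture medium and with the dates in the sample titles, so a difference between cell types is also one between media and dates. P-values were adjusted over all genes of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05 and no threshold on the fold change. Changes are given as log2 fold change ± SE, where the SE is the fold change divided by the root of the quasi-likelihood F statistic, and intervals are at 95%. Levels are counts scaled to the library total (CPM) on TMM-scaled libraries, as mean ± SD. Intervals of fold changes come from the fit and include the spread between replicates, while floors on counts cover counting error only. A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group.

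The comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. There were 12 pathway lists: LXR targets in cholesterol efflux and lipid transport, SREBP-1c and fatty acid synthesis, cholesterol biosynthesis enzymes, other SREBP-2 targets, inflammatory response, interferon response, alternative activation, ER stress and amino acid stress response, PXR and CAR targets, FXR targets and bile acid handling, PPAR-alpha targets and fatty acid oxidation, and cell cycle. A further 12 lists held markers of hepatocytes, macrophages and Kupffer cells, stellate cells and fibroblasts, endothelial cells, cholangiocytes, B cells, T and NK cells, neutrophils, eosinophils, mast cells, mesothelial cells and dendritic cells. Adgre1 and Ly6g were absent from the macrophage table, and Siglecf was read there under the symbol Siglec5. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and again with an estimated correlation, adjusted within the pathway or the marker lists. The fry test was run beside it. Its p-value asks whether a list's genes move on balance one way and its mixed p-value whether they change in either direction, and neither compares a list with other genes. Named genes came from a rule: Abca1, Abcg1, Srebf1, Scd1, Fasn and Mylip always, up to 4 members per pathway list with the largest change past the threshold, and the 10 rising and 10 falling genes with the largest change past the threshold, a mean of at least 1 CPM and groups whose replicates did not overlap, leaving out provisional symbols. Marker genes could be named by list. Some genes that the rule names are left out of the text, while the counts and tests of lists and of all genes hold every gene tested.

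Sequencing depth differed between groups. Exon counts per library ranged from 3.86 M to 15.69 M in macrophages (median 7.34 M) and from 6.63 M to 18.63 M in hepatocytes (median 14.04 M), and the macrophage vehicle and desmosterol libraries were deeper than most others. With every macrophage library thinned to 3.86 M, calls numbered 628, 982, 3204, 1114 and 1202 for desmosterol, DMHCA, MePipHCA, GW3965 and T0901317, against 1097, 1350, 4091, 1527 and 1482 at full depth. To see what this depth could detect, 200 genes were changed in simulated counts built on the DMHCA comparison. With edgeR, of 67, 67 and 66 genes changed 1.5-, 2- and 4-fold, the share called was 58.2%, 89.6% and 95.5% in macrophages and 44.8%, 64.2% and 83.3% in hepatocytes. For the difference between cell types it was 29.9%, 64.2% and 72.7%. False calls made up 3.4%, 5% and 3.4% of all calls. Camera called a simulated list of 15 genes lowered 1.5-fold in each of the 3 settings and none of 11 unchanged lists. Simulated genes varied independently, so this does not cover lists whose genes vary together.

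Because ligands share a vehicle group, their changes correlate even without a shared response. The correlation and covariance of each pair of ligands were therefore set against 20 draws simulated with shared controls and no response, and shared calls against the number that independence gives. For macrophages they were also set against 20 draws in which each ligand kept its called changes but on other genes of like level, a test chosen after seeing the data. Replicate numbers were not used as a pairing in the comparisons, because the labels do not say what they mark. As a check, libraries with the same number in different groups were correlated after removing group means. They correlated by −0.209 to 0.235 in macrophages (median 0.026) and −0.099 to 0.143 in hepatocytes (median 0.008). In hepatocytes the 2 numbers give the same value by construction. Best matches were with a library of the same number for 10 of 18 macrophage and 10 of 12 hepatocyte libraries, so a pairing was not excluded. The alternatives tried were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Leaving out the 4 libraries that stood apart from their group (macrophage desmosterol replicate 2 and T0901317 replicate 2, hepatocyte desmosterol replicate 1 and T0901317 replicate 2) was chosen after seeing the data. Where a library left out leaves 1 in a group, that lone library is assumed to vary like the other groups. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the tables, and matplotlib 3.10.9 drew the figures.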

Results

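Messenger RNA was measured in primary mouse cells of 2 kinds, macrophages drawn into the peritoneum with thioglycollate and hepatocytes. Cells were first kept for 24 h in medium with lipid-deficient serum, 50 uM mevalonate and 10 uM mevastatin, an inhibitor of cholesterol synthesis, and then held with a ligand for 18 to 20 h. The ligands were desmosterol at 10 uM, a late intermediate of cholesterol synthesis that activates the liver X receptors (LXR), the cholenamides DMHCA and MePipHCA at 1 uM, which mimic it and differ from each other in the amide, and the synthetic LXR agonists GW3965 and T0901317 at 1 uM. Each macrophage group had 3 replicates and each hepatocyte group 2, with 1 vehicle group per cell type. Exon counts per macrophage library, in M counts, were 10.55, 15.69 and 11.66 for vehicle, 10.31, 13.43 and 9.75 for desmosterol, 3.86, 5.78 and 7.69 for DMHCA, 4.65, 4.24 and 6.8 for MePipHCA, 4.7, 6.98 and 8.89 for GW3965 and 4.02, 4.01 and 11.45 for T0901317. Hepatocyte libraries held 12.85 and 6.63 for vehicle, 11.05 and 15.96 for desmosterol, 13.85 and 15.26 for DMHCA, 11.96 and 18.63 for MePipHCA, 14.48 and 17.77 for GW3965 and 14.22 and 11.05 for T0901317. Macrophage libraries detected 13484 to 15814 genes and hepatocyte libraries 13983 to 15118.

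Genes followed in every comparison lie on mm10 at chromosome 4, 53030789 to 53159895 for Abca1 (NM_013454), chromosome 17, 31057694 to 31117981 for Abcg1 (NM_009593), chromosome 13, 45389742 to 45411940 for Mylip (NM_153789), chromosome 11, 60199084 to 60220627 for Srebf1 (NM_011480, with ends of 60199089 and 60220604 in the macrophage table), chromosome 19, 44394450 to 44407709 for Scd1 (NM_009127) and chromosome 11, 120805958 to 120824547 for Fasn (NM_007988). Macrophage values rest on n = 3 libraries per group and hepatocyte values on n = 2. A gene rose or fell only where its adjusted p was below 0.05. Unless an adjusted p with an estimated correlation is given beside it, a named camera call held with that correlation too.

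Desmosterol against vehicle in macrophages asks how the natural sterol acts on the LXR and SREBP genes of these cells. Abca1, the pump that loads cholesterol onto lipoproteins, rose 7.96-fold from 153 ± 11.6 to 1221 ± 18.9 CPM (SD, n = 3), a log2 fold change of 2.99 ± 0.05. Abcg1, a further cholesterol exporter, rose by 1.94 ± 0.05 and Mylip, a ubiquitin ligase, by 2.73 ± 0.07. Srebf1, which encodes the SREBP-1 factor of lipid synthesis, rose by only 0.47 ± 0.06, while the desaturase Scd1 fell by 0.92 ± 0.10 and the synthase Fasn by 1.23 ± 0.07. Of 20 cholesterol biosynthesis enzymes 19 fell, also when adjusted over the list alone, with a median of −1.69 (camera adjusted p = 2e-49), among them Fdps (−2.32 ± 0.14) and Hsd17b7 (−2.25 ± 0.16). Of 9 other SREBP-2 targets 8 fell (1 up and 8 down adjusted over the list alone, adjusted p = 9e-16), among them Insig1, which retains SREBP in the endoplasmic reticulum (−1.91 ± 0.07). Of 14 LXR targets 11 rose (11 adjusted over the list alone, median 0.70, adjusted p = 2.5e-32), including Arl4c (1.34 ± 0.07), a small GTPase. The list for SREBP-1c and fatty acid synthesis had 3 of 14 genes up and 8 down, and as many adjusted over the list alone (adjusted p = 3.5e-05), with the elongase Elovl6 at −1.40 ± 0.14. Among 13 stress genes 4 rose (6 adjusted over the list alone, adjusted p = 0.0037), with Asns at 0.95 ± 0.18 and the chaperone Hspa5 at 0.36 ± 0.05.

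Outside these lists the largest rises with desmosterol in macrophages included Cd38, an ectoenzyme that consumes NAD (2.12 ± 0.16), and Lbp, which binds bacterial lipopolysaccharide (1.84 ± 0.24). The cytokine Il1a rose by 1.60 ± 0.09 while the receptor Tlr2 fell by 0.69 ± 0.12, and the inflammatory list had 2 of 17 genes up and 3 down (3 and 4 adjusted over the list alone, adjusted p = 0.698, with a median of −0.03, a mean of 0.05 and an upward test). Interferon genes had 2 of 16 down (4 adjusted over the list alone, adjusted p = 0.0375, and 0.369 with an estimated correlation). Irf7, 1 of the 2, stood at 18.61 ± 11.4 CPM in vehicle and 10.93 ± 2.29 with desmosterol, and its replicates overlapped. No cell cycle gene of 11 passed (adjusted p = 0.367). Of 6 markers of stellate cells and fibroblasts none passed (adjusted p = 0.854), and of 8 macrophage and Kupffer cell markers 1 fell, the receptor Csf1r (−0.31 ± 0.05, adjusted p of the list 0.854). Stab2, an endothelial marker and scavenger receptor, rose by 1.39 ± 0.24. In all, 569 genes rose and 528 fell, and replicates did not overlap for 25.1% of genes, against 10% by chance. Without vehicle replicate 2 the sum of 1097 calls dropped to 665, and with every library thinned to 1 depth to 628, where 2 stress genes rose in place of 4.

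DMHCA against vehicle in macrophages asks whether a mimetic acts as the sterol does. Abca1 rose 13.6-fold to 2086 ± 81.1 CPM (3.76 ± 0.05), Abcg1 by 2.49 ± 0.05 and Mylip by 3.35 ± 0.07. Srebf1 rose by 1.53 ± 0.06 and Scd1 by 0.98 ± 0.09, whereas Fasn did not pass (−0.17, 95% interval −0.32 to −0.03, adjusted p = 0.131, with 0.0326 to 0.584 over all settings and a call only without vehicle replicate 1). Of 14 LXR targets 13 rose (13 adjusted over the list alone, median 1.07, adjusted p = 3.7e-38), with Pltp, which moves phospholipids between lipoproteins, at 2.17 ± 0.06. Among 20 cholesterol biosynthesis enzymes 1 rose and 18 fell (1 and 19 adjusted over the list alone, median −1.79, adjusted p = 4.5e-36), with Cyp51 at −2.18 ± 0.08 and Sqle at −2.13 ± 0.08. Of 9 other SREBP-2 targets 6 fell (1 up and 7 down adjusted over the list alone, adjusted p = 1.8e-10), among them Insig1 (−1.53 ± 0.07). The fatty acid synthesis list moved both ways, with 6 genes up and 5 down (6 and 6 adjusted over the list alone, adjusted p = 0.21): the desaturase Scd2 rose by 1.75 ± 0.06 and Fads2, a desaturase too, fell by 1.78 ± 0.28. Of 13 stress genes 2 rose (5 adjusted over the list alone), including Hspa5 (0.52 ± 0.05), with an adjusted p of 0.0468 for the list that was 0.0881 with an estimated correlation.

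Lbp (3.38 ± 0.22), Cd38 (3.32 ± 0.16) and Il18bp, a decoy of interleukin 18 (2.87 ± 0.11), were among the largest rises with DMHCA in macrophages. Il1a rose by 1.66 ± 0.09 and Tnf fell by 1.23 ± 0.21, and the inflammatory list had 2 of 17 genes up and 6 down (2 and 8 adjusted over the list alone, adjusted p = 0.274). Interferon genes had 3 of 16 down, as many adjusted over the list alone (adjusted p = 0.0373, and 0.354 with an estimated correlation). Irf7, 1 of the 3, stood at 18.61 ± 11.4 CPM in vehicle and 11.75 ± 0.568 with DMHCA, and its replicates overlapped. All 6 markers of stellate cells and fibroblasts fell, also adjusted over the list alone (median −0.69, adjusted p = 2e-05, and 0.0645 with an estimated correlation), with the contractile gene Acta2 at −1.35 ± 0.20 and the collagen Col1a1 at −0.77 ± 0.13. Of 8 macrophage and Kupffer cell markers 3 fell (adjusted p = 0.0806), and the mesothelial and cholangiocyte lists did not pass (adjusted p = 0.0806 and 0.147). Calls comprised 669 genes up and 681 down, with replicates apart for 27.5% of genes against 10% by chance. Without vehicle replicate 2 there were 898 calls in place of 1350.

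MePipHCA against vehicle in macrophages asks the same of the other mimetic. Abca1 rose 18.3-fold to 2802 ± 60.1 CPM (4.19 ± 0.05), Abcg1 by 2.83 ± 0.05 and Mylip by 3.49 ± 0.07. Srebf1 rose by 0.89 ± 0.07 and Scd1 by 0.84 ± 0.09, while Fasn did not pass (−0.01, 95% interval −0.15 to 0.14, adjusted p = 0.951). Among 20 cholesterol biosynthesis enzymes 1 rose and 19 fell, as many adjusted over the list alone (median −2.29, adjusted p = 1.1e-21), with Fdps at −3.57 ± 0.19 and Sqle at −3.33 ± 0.10. Of 9 other SREBP-2 targets 1 rose and 7 fell (1 and 8 adjusted over the list alone, adjusted p = 2.6e-08), and Stard4, which carries cholesterol between membranes, fell by 3.17 ± 0.17. Of 14 LXR targets 12 rose, as many adjusted over the list alone (median 1.68, adjusted p = 1.1e-17), with Arl4c at 2.74 ± 0.07. The fatty acid synthesis list had 6 genes up and 5 down, as many adjusted over the list alone (adjusted p = 0.903, with a median of 0.00 and a mean of −0.39 against an upward test), and Fads2 fell by 3.13 ± 0.36. Of 13 genes of ER and amino acid stress 12 rose (12 up and 1 down adjusted over the list alone, median 1.55, adjusted p = 1.1e-13). Among them were the glutathione-degrading Chac1 (4.22 ± 0.33), the pseudokinase Trib3 (3.72 ± 0.14), the asparagine synthetase Asns (3.37 ± 0.16) and Ddit3, the factor CHOP (2.28 ± 0.08).

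Further MePipHCA changes in macrophages took in Soat2, which esterifies cholesterol (16.0-fold higher), Lbp (3.52 ± 0.21) and Cd38 (3.52 ± 0.15), and the serpin Serpina3g had 0 counts against 112 in vehicle, at least 14.5-fold lower. Il1a rose by 2.46 ± 0.09 and the chemokine Ccl2 fell by 3.24 ± 0.38, with 4 of 17 inflammatory genes up and 5 down (5 and 5 adjusted over the list alone, adjusted p = 0.301). Interferon genes had 1 of 16 up and 12 down (2 and 12 adjusted over the list alone, median −0.83, adjusted p = 0.0011, and 0.142 with an estimated correlation), among them Oasl2 (−1.20 ± 0.11). Of 11 cell cycle genes 10 fell (11 adjusted over the list alone, median −1.50, adjusted p = 4.9e-05), with the proliferation marker Mki67 at −2.44 ± 0.20. All 6 markers of stellate cells and fibroblasts fell, also adjusted over the list alone (median −1.51, adjusted p = 1.9e-06): Acta2 fell by 4.30 ± 0.32, Tagln by 2.91 ± 0.30, Col1a1 by 1.55 ± 0.15 and Dcn by 1.35 ± 0.14. All 4 mesothelial markers fell, with Wt1 at −1.81 ± 0.27 (adjusted p = 0.00308), and 2 of 3 cholangiocyte markers fell, with Sox9 at −2.86 ± 0.48 (adjusted p = 0.0137). Of 8 macrophage and Kupffer cell markers 6 fell, also adjusted over the list alone (median −0.42, adjusted p = 0.000158), with Csf1r at −0.88 ± 0.05 and Itgam at −0.74 ± 0.05. The T and NK cell list had 1 tested member, Cd4, which fell. Counts of 1980 genes up and 2111 down were the largest of the ligands, and replicates were apart for 48.1% of genes against 10% by chance.

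GW3965 and T0901317 against vehicle in macrophages ask how synthetic agonists act on the same genes. Abca1 rose 19.8-fold with GW3965 (4.31 ± 0.05) and 20.1-fold with T0901317 (4.33 ± 0.05), Abcg1 rose by 2.84 ± 0.05 and 2.86 ± 0.05, and Mylip by 3.57 ± 0.07 and 3.69 ± 0.07. Srebf1 rose by 2.59 ± 0.06 and 2.60 ± 0.06, Scd1 by 4.29 ± 0.07 and 4.52 ± 0.07, and Fasn by 2.61 ± 0.07 and 2.45 ± 0.07. Of 14 LXR targets 12 rose with GW3965 (12 up and 1 down adjusted over the list alone, median 1.82, adjusted p = 2.7e-36). With T0901317 12 rose and 1 fell, as many adjusted over the list alone (median 1.69, adjusted p = 3.2e-33). Of 14 genes of SREBP-1c and fatty acid synthesis 11 rose with GW3965 and 10 with T0901317, each 11 adjusted over the list alone (adjusted p = 5e-21 and 4.6e-21), led after Scd1 by Scd2 (3.73 ± 0.06 and 3.96 ± 0.06). Of 20 cholesterol biosynthesis enzymes 2 rose and 4 fell with each. Adjusted over the list alone these counts were 2 and 5 with GW3965 (adjusted p = 0.909, median 0.03, mean −0.03, test downward) and 2 and 4 with T0901317 (adjusted p = 0.93, median 0.01, mean −0.01, test upward). Of 9 other SREBP-2 targets 3 and 2 rose, each 3 adjusted over the list alone (adjusted p = 0.0614 and 0.068).

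Cd38 (4.31 ± 0.14 and 4.26 ± 0.14) and Lbp (4.09 ± 0.20 and 4.02 ± 0.20) led the rises outside the lists for GW3965 and T0901317 in macrophages, and the glycosyltransferase Galnt9 fell with each (−1.31 ± 0.18 and −1.82 ± 0.20). Inflammatory genes had 2 of 17 up and 4 down with GW3965 (3 and 4 adjusted over the list alone, adjusted p = 0.823) and 4 up and 4 down with T0901317 (4 and 5 adjusted over the list alone, adjusted p = 0.903). The adhesion molecule Icam1 fell by 0.76 ± 0.11 and 0.99 ± 0.12. Of 13 stress genes 4 and 5 rose (5 and 7 adjusted over the list alone, adjusted p = 0.0506 and 0.0313, the latter 0.0568 with an estimated correlation). Interferon genes had 2 and 3 of 16 down (adjusted p = 0.217 and 0.0702) and cell cycle genes 3 and 2 of 11 (adjusted p = 0.0614 and 0.427). Of 8 macrophage and Kupffer cell markers 5 and 6 fell, as many adjusted over the list alone (adjusted p = 0.000102 and 7.4e-05), with Csf1r at −0.43 ± 0.05 and −0.51 ± 0.05. Markers of stellate cells and fibroblasts did not pass as a list (adjusted p = 0.168 and 0.684). Calls numbered 755 up and 772 down with GW3965 and 726 up and 756 down with T0901317, with replicates apart for 28.4% and 26.2% of genes against 10% by chance.

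Of smaller pathway lists in macrophages, PXR and CAR targets passed with the synthetic agonists. Of the 5 genes 3 fell with T0901317 (adjusted p = 0.00982) and 3 with GW3965 (adjusted p = 0.0384, and 0.0794 with an estimated correlation). Genes of this list moved both ways with the sterols: 1 rose and 2 fell with desmosterol, 1 and 3 with DMHCA and 1 and 2 with MePipHCA (adjusted p = 0.792, 0.274 and 0.257 for the list). In the order desmosterol, DMHCA, MePipHCA, GW3965, T0901317, camera gave adjusted p values of 0.792, 0.323, 0.223, 0.26 and 0.245 for 3 FXR targets and bile acid genes. In that order they were 0.281, 0.744, 0.115, 0.305 and 0.772 for 6 PPAR-alpha targets, and 0.698, 0.548, 0.23, 0.481 and 0.205 for 5 genes of alternative activation. Angptl4, a lipase inhibitor, fell with MePipHCA (−1.85 ± 0.24) and with desmosterol (−0.94 ± 0.18). Of hepatocyte markers only Trf, the iron carrier transferrin, was tested, and it fell with MePipHCA (−0.45 ± 0.06). It rose with DMHCA (0.21 ± 0.06, adjusted p = 0.0113), a call lost without DMHCA replicate 3 (0.174) or vehicle replicate 2 (0.0687), with 0.000168 at the lowest. With T0901317 it rose too (0.18 ± 0.06, adjusted p = 0.0352), a call lost without T0901317 replicate 1 (0.0569), 2 (0.165) or 3 (0.0513) or vehicle replicate 1 (0.085) or 2 (0.147), with 0.00815 at the lowest. Of neutrophil markers only S100a8 was tested. It was not called with MePipHCA (−0.18 ± 0.20) and was higher with DMHCA than with T0901317 (1.06 ± 0.22, adjusted p = 0.00125). Against vehicle it fell with T0901317 (−0.72 ± 0.21, adjusted p = 0.0131), a call lost without T0901317 replicate 2 (0.0574) or 3 (0.178) or vehicle replicate 1 (0.0667), with 0.00491 at the lowest. Of eosinophil markers only Siglecf was tested, and it was not called. Genes for B cells, mast cells and dendritic cells were too scarce to test.

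MePipHCA against DMHCA at the matched dose of 1 uM asks whether the mimetics act alike in macrophages. Abca1 was 1.34-fold higher with MePipHCA (0.43 ± 0.05, 95% interval 0.33 to 0.52) and Abcg1 1.26-fold (0.34 ± 0.05). Mylip did not differ past the threshold (0.14, 95% interval 0.02 to 0.26, adjusted p = 0.0836), nor did Scd1 (−0.14, 95% interval −0.33 to 0.04, adjusted p = 0.293) or Fasn (0.16, 95% interval 0.01 to 0.32, adjusted p = 0.132). Over all settings Fasn had adjusted p values of 0.0401 to 0.515, the lowest and only call being without DMHCA replicate 1. Srebf1 was lower with MePipHCA by a log2 difference of −0.65 ± 0.06. Of 20 cholesterol biosynthesis enzymes 14 were lower (15 adjusted over the list alone, median −0.63, adjusted p = 1.5e-11), as were 5 of 9 other SREBP-2 targets, with as many adjusted over the list alone (adjusted p = 5.5e-05), among them Srebf2, which encodes SREBP-2 (−1.13 ± 0.08). Of 13 stress genes 11 were higher (12 adjusted over the list alone, median 1.56, adjusted p = 2.6e-16), with Chac1 at 4.67 ± 0.43, Trib3 at 3.36 ± 0.16 and Asns at 2.79 ± 0.17. LXR targets went both ways, with 6 of 14 higher and 4 lower (7 and 4 adjusted over the list alone, adjusted p = 0.0487, and 0.175 with an estimated correlation). Fatty acid synthesis had 1 gene higher and 7 lower, as many adjusted over the list alone (adjusted p = 0.00647, and 0.0995 with an estimated correlation), with Scd2 at −1.02 ± 0.06. All 6 markers of stellate cells and fibroblasts were lower (adjusted p = 5.1e-05), with Acta2 at −2.94 ± 0.41, as were 5 of 8 macrophage and Kupffer cell markers (6 adjusted over the list alone, adjusted p = 0.000281). Cell cycle genes had 4 of 11 lower (5 adjusted over the list alone, adjusted p = 0.000521), with Mki67 at −2.02 ± 0.23. In all, 1240 genes were higher and 1399 lower.

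Each mimetic was set against T0901317 at the same dose in macrophages to compare them with a full synthetic agonist. With DMHCA Abca1 was lower by a log2 difference of −0.56 ± 0.05, Abcg1 by −0.37 ± 0.05 and Mylip by −0.35 ± 0.06. The gap was wider for Scd1 (−3.54 ± 0.07), Fasn (−2.62 ± 0.07), Srebf1 (−1.07 ± 0.06) and Scd2 (−2.20 ± 0.06). With DMHCA 12 of 14 genes of fatty acid synthesis were lower (13 adjusted over the list alone, adjusted p = 1.5e-34) and 18 of 20 cholesterol biosynthesis enzymes (19 adjusted over the list alone, adjusted p = 3.4e-46). Of 14 LXR targets 2 were higher and 10 lower (2 and 11 adjusted over the list alone, adjusted p = 1.9e-09). All 6 markers of stellate cells and fibroblasts were lower with DMHCA (adjusted p = 3.5e-07). With MePipHCA Abcg1 did not differ from T0901317 (−0.03, 95% interval −0.12 to 0.06, adjusted p = 0.68) and Mylip was lower by −0.21 ± 0.06. Abca1 was lower by −0.14 ± 0.05 (adjusted p = 0.0224), a call lost without MePipHCA replicate 1 (adjusted p = 0.0921), MePipHCA replicate 3 (0.0899), T0901317 replicate 1 (0.0997) or T0901317 replicate 3 (0.0652), against 0.00113 at the lowest over all settings. Scd1 (−3.68 ± 0.07) and Fasn (−2.46 ± 0.07) were lower, as were all 14 genes of fatty acid synthesis (adjusted p = 4.7e-18) and all 20 cholesterol biosynthesis enzymes (adjusted p = 1.8e-27), with the same counts adjusted over the list alone. Most LXR targets differed (3 higher and 8 lower, 4 and 8 adjusted over the list alone), but camera did not call the list (adjusted p = 0.146). Camera asks only whether a list shifts more than other genes do. Fibroblast matrix genes had a median log2 difference of −1.502 with MePipHCA over T0901317, and contractile genes had one of −3.515. Of 13 stress genes 11 were higher with MePipHCA (12 adjusted over the list alone, adjusted p = 2.5e-14) and 1 with DMHCA (2 up and 1 down adjusted over the list alone, adjusted p = 0.84). Between DMHCA and T0901317 260 genes were higher and 331 lower, 591 in sum and 336 without DMHCA replicate 3. For MePipHCA and T0901317 1390 were higher and 1605 lower.

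DMHCA was compared with desmosterol in macrophages, at doses that differed (1 uM and 10 uM), so that dose and ligand cannot be told apart. With DMHCA Abca1 was 1.71-fold higher (0.77 ± 0.05), Abcg1 higher by 0.55 ± 0.05, Mylip by 0.62 ± 0.06, Srebf1 by 1.06 ± 0.06, Scd1 by 1.90 ± 0.10 and Fasn by 1.06 ± 0.08. Of 14 LXR targets 11 were higher (12 adjusted over the list alone, median 0.52, adjusted p = 6.6e-28), with Pltp at 1.24 ± 0.05, and of 14 genes of fatty acid synthesis 7 (8 adjusted over the list alone, adjusted p = 7.4e-13), with Scd2 at 2.00 ± 0.06. Cholesterol biosynthesis enzymes did not differ as a list (1 higher and 1 lower of 20, 2 and 3 adjusted over the list alone, adjusted p = 0.995, median 0.01 and mean −0.01). Other SREBP-2 targets had 2 higher of 9 (4 up and 1 down adjusted over the list alone, median 0.15 and mean −0.14, adjusted p = 0.0451, and 0.31 with an estimated correlation). All 6 markers of stellate cells and fibroblasts were lower with DMHCA (adjusted p = 4e-09), with Acta2 at −1.44 ± 0.20. Of 271 calls 123 were higher and 148 lower, with 158 calls left without DMHCA replicate 1 and 167 without DMHCA replicate 3.

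Ligands that share a vehicle group correlate in part for that reason. Across genes, which are not independent replicates, log2 fold changes of GW3965 and T0901317 in macrophages had r = 0.774 against 0.386 simulated with shared controls alone, and a covariance of 0.0895 against 0.0132. They shared 537 rising and 547 falling genes, where independence gives 47.5 and 50.6, and 0 in opposite directions. DMHCA and MePipHCA had r = 0.646 against 0.35, a covariance of 0.139 against 0.0132, 469 shared rises and 528 shared falls (115 and 125 by independence) and 64 genes in opposite directions. Desmosterol and DMHCA had r = 0.622 against 0.412, a covariance of 0.0558 against 0.0132, and 394 shared rises and 284 shared falls (33 and 31.1 by independence). MePipHCA and T0901317 had r = 0.374 against 0.364, a covariance of 0.081 against 0.0135, 453 shared rises and 487 shared falls (125 and 138 by independence) and 128 genes in opposite directions. Desmosterol and MePipHCA had r = 0.389 against 0.41, a covariance of 0.0644 against 0.0135, 389 shared rises and 319 shared falls (97.6 and 96.6 by independence) and 74 genes in opposite directions. The other 5 macrophage pairs had r of 0.447 to 0.633 against 0.369 to 0.432. With the called changes of each ligand moved in simulated counts to other genes of like level, and the controls still shared, macrophage pairs shared 41.6 to 132 rises and 32 to 147 falls on average over 20 draws, against 321 to 537 and 174 to 547 in the data.

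**Figure D1:**
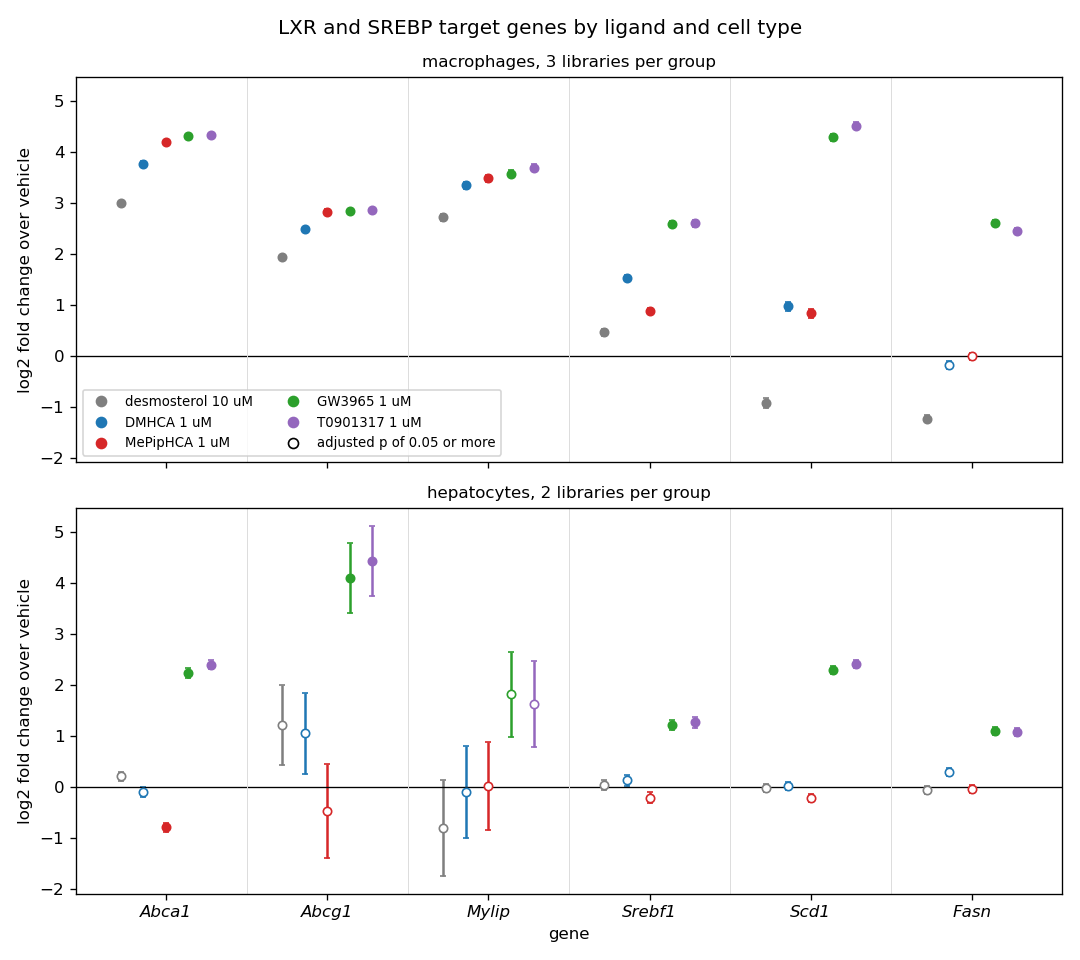
Log2 fold change over vehicle of Abca1, Abcg1, Mylip, Srebf1, Scd1 and Fasn for each ligand in macrophages (n = 3 per group) and hepatocytes (n = 2), with points for the fitted value, bars for its SE and open symbols where the adjusted p was 0.05 or more. Scd1 with T0901317 in macrophages lies highest, at 4.52.

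Desmosterol and DMHCA against vehicle in hepatocytes ask whether these cells respond as macrophages do. With desmosterol none of Abca1, Abcg1, Mylip, Srebf1, Scd1 and Fasn passed, with Abca1 at 0.21 (95% interval 0.03 to 0.40, adjusted p = 0.519) around a vehicle level of 174 ± 22.4 CPM (SD, n = 2). Angptl4 rose by 0.69 ± 0.11, and the heme oxygenase Hmox1 fell by 0.87 ± 0.08 and the cystine carrier Slc7a11 by 0.86 ± 0.11. Gpnmb, a glycoprotein abundant in macrophages, fell by 4.04 ± 0.74 (adjusted p = 0.0071), a call that rested on vehicle replicate 1 (−0.86 and adjusted p = 0.845 without it) and on desmosterol replicate 2 (−3.52 and adjusted p = 0.127 without it), with adjusted p from 1.8e-18 to 0.845 over all settings. Among 20 cholesterol biosynthesis enzymes 1 fell (6 adjusted over the list alone, adjusted p = 0.000163, and 0.0634 with an estimated correlation) and of 18 LXR targets 1 rose (2 adjusted over the list alone, adjusted p = 0.0222, and 0.12 with an estimated correlation). Interferon genes had 1 of 18 down and cell cycle genes 0 of 12 (adjusted p = 0.0244 for each, and 0.443 and 0.233 with an estimated correlation). Desmosterol calls came to 27 up and 21 down, a sum of 48 that dropped to 15 without desmosterol replicate 2, 22 without vehicle replicate 1 and 17 without vehicle replicate 2. With DMHCA 0 genes passed with edgeR and 0 with DESeq2, and 615 had an unadjusted p below 0.05. Without DMHCA replicate 2 there were 27 calls and without vehicle replicate 2 there were 6. Intervals with DMHCA ran from −0.28 to 0.10 for Abca1, −0.08 to 0.36 for Srebf1, −0.12 to 0.18 for Scd1 and 0.14 to 0.46 for Fasn. Abcg1 and Mylip were scarce in hepatocytes, so that changes as large as 2.69 for Abcg1 were not excluded. No pathway or marker list passed with DMHCA, where the lowest adjusted p of a pathway list was 0.136 and 1 gene of the cholesterol, LXR and fatty acid synthesis lists each rose adjusted over the list alone.

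MePipHCA against vehicle in hepatocytes asks the same of the other mimetic in these cells. Abca1 fell from 174 ± 22.4 to 101 ± 1.75 CPM (−0.79 ± 0.09, adjusted p = 4.5e-06), while Srebf1 did not pass (−0.20, 95% interval −0.42 to 0.01) nor did Scd1 (−0.20 ± 0.07) or Fasn (−0.02 ± 0.08). In the list of 20 cholesterol biosynthesis enzymes 16 fell (18 adjusted over the list alone, median −0.68, adjusted p = 4.5e-27), among them Lss (−1.08 ± 0.10), Hmgcs1 (−0.96 ± 0.08) and Acat2 (−0.99 ± 0.11). Of 9 other SREBP-2 targets 4 fell (8 adjusted over the list alone, adjusted p = 1.8e-07), with Insig1 at −1.04 ± 0.10 and the phosphatase Lpin1 at −1.08 ± 0.13. Of 19 genes of fatty acid synthesis 6 fell (11 adjusted over the list alone, median −0.37, adjusted p = 1.1e-10), with Scd2 at −1.78 ± 0.24 and the acyltransferase Gpam at −0.72 ± 0.10. Of 18 LXR targets 1 rose and 2 fell (3 and 3 adjusted over the list alone, adjusted p = 0.11). Of 14 stress genes 5 rose (8 adjusted over the list alone, median 0.36, adjusted p = 2.3e-07), with Trib3 at 0.78 ± 0.13. The mitochondrial folate enzyme Aldh1l2 rose by 2.12 ± 0.32, and Id2, an inhibitor of differentiation factors, fell by 1.76 ± 0.23. Of 12 hepatocyte markers 5 fell (9 adjusted over the list alone, median −0.34, adjusted p = 1.8e-05), and of 12 cell cycle genes 3 (5 adjusted over the list alone, adjusted p = 2.3e-07), with Top2a at −1.24 ± 0.21. PPAR-alpha targets had 1 of 14 down (5 adjusted over the list alone, adjusted p = 0.00629), and FXR targets 1 of 11 (adjusted p = 0.0367, and 0.146 with an estimated correlation). Calls were 104 up and 182 down, 286 in sum, and 121 without MePipHCA replicate 1, 114 without MePipHCA replicate 2 and 143 without vehicle replicate 1.

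GW3965 and T0901317 in hepatocytes ask whether these cells carry a working LXR response. Abca1 rose 4.74-fold to 828 ± 26.2 CPM (2.24 ± 0.09) with GW3965 and 5.3-fold (2.40 ± 0.09) with T0901317. Abcg1 rose from 6 counts in vehicle by 4.10 ± 0.69 and 4.44 ± 0.69, Srebf1 by 1.22 ± 0.10 and 1.27 ± 0.10, Scd1 by 2.30 ± 0.08 and 2.42 ± 0.08, and Fasn by 1.11 ± 0.08 and 1.08 ± 0.08. Mylip did not pass (1.82, 95% interval 0.11 to 3.54, adjusted p = 0.547, and 1.63, 95% interval −0.10 to 3.36, adjusted p = 0.437). Of 18 LXR targets 6 rose with each (7 adjusted over the list alone, adjusted p = 2.4e-08 and 6.3e-08), with the lipase Lpl at 2.25 ± 0.38 with GW3965. Of 19 genes of fatty acid synthesis 8 rose with each (12 up and 1 down adjusted over the list alone, adjusted p = 1.1e-16 and 6.7e-14), with Scd2 at 1.71 ± 0.20 and 2.10 ± 0.20. Cholesterol biosynthesis enzymes had 1 of 20 up with GW3965 (2 up and 3 down adjusted over the list alone, adjusted p = 0.647) and 1 up and 2 down with T0901317 (4 and 2 adjusted over the list alone, adjusted p = 0.687). Of 9 other SREBP-2 targets 3 and 4 rose (4 and 5 adjusted over the list alone, adjusted p = 0.00236 and 0.000429, and 0.145 and 0.0862 with an estimated correlation), with Insig1 at 0.67 ± 0.10 and 0.57 ± 0.10. Of 14 stress genes 0 and 2 rose (5 and 3 adjusted over the list alone, adjusted p = 0.000511 and 0.000751, and 0.145 and 0.169 with an estimated correlation). Calls were 48 up and 15 down with GW3965, 63 in sum, with 28 left without GW3965 replicate 1 and 41 without GW3965 replicate 2. With T0901317 they were 64 up and 60 down, 124 in sum, with 48 left without T0901317 replicate 1, 76 without T0901317 replicate 2 and 50 without vehicle replicate 2. Fold changes of GW3965 and T0901317 had r = 0.554 across genes against 0.553 simulated with shared controls, with a covariance of 0.204 against 0.127, 36 shared rises and 10 shared falls where independence gives 0.233 and 0.0683. The other 9 hepatocyte pairs of ligands had r below the simulated value, 0.448 to 0.506 against 0.545 to 0.565. Their covariances were above the simulated ones, 0.14 to 0.17 against 0.126 to 0.129. Of these pairs MePipHCA and T0901317 shared 6 rises and 16 falls, where independence gives 0.505 and 0.829, with 15 genes in opposite directions.

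Other lists in hepatocytes, in the order desmosterol, DMHCA, MePipHCA, GW3965, T0901317, gave camera adjusted p values of 0.276, 0.146, 0.428, 0.174 and 0.687 for 11 PXR and CAR targets. They were 0.276, 0.685, 0.311, 0.869 and 0.687 for 12 inflammatory genes and 0.731, 0.136, 0.913, 0.879 and 0.65 for 4 genes of alternative activation. Hepatocyte markers did not pass with desmosterol, DMHCA, GW3965 or T0901317 (adjusted p = 0.4, 0.942, 0.515 and 0.342). Among 11 macrophage and Kupffer cell markers 1 rose with GW3965, and the list had an adjusted p of 0.322. Marco (−0.64 ± 0.26), Vsig4 (0.09 ± 0.69) and Cd68 (0.06 ± 0.15) did not pass. Cd5l, a member of the LXR list, rose with GW3965 by 3.38 ± 0.45. Of 54 genes abundant in macrophages and scarce in hepatocytes, 40 and 33 lay above the other hepatocyte libraries in GW3965 replicates 1 and 2. A part from macrophages in the GW3965 rises of Cd5l and Lpl was therefore not separated. No endothelial or cholangiocyte marker passed with any ligand. Of stellate, mast and dendritic cell markers Reln, Tagln, Kit and Zbtb46 were the only ones tested, and none was called.

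The mimetics were also compared at 1 uM in hepatocytes. With MePipHCA Abca1 was lower than with DMHCA by a log2 difference of −0.70 ± 0.09 (95% interval −0.89 to −0.51). Srebf1 did not differ past the threshold (−0.34, 95% interval −0.56 to −0.13, adjusted p = 0.0663), nor did Scd1 (−0.23, 95% interval −0.38 to −0.08, adjusted p = 0.0809), Abcg1 (95% interval −3.08 to 0.02) or Mylip (95% interval −1.61 to 1.83). Over all settings the adjusted p of Srebf1 ran from 0.00614, without DMHCA replicate 2, to 0.534, and that of Scd1 from 0.0226, with DESeq2, to 0.349, with 0.0331 without DMHCA replicate 1. Fasn was lower by −0.32 ± 0.08 (adjusted p = 0.0153), a call lost without DMHCA replicate 1 (adjusted p = 0.114), MePipHCA replicate 1 (0.11) or MePipHCA replicate 2 (0.171), with 0.000101 at the lowest over all settings. Of 20 cholesterol biosynthesis enzymes 17 were lower (19 adjusted over the list alone, median −0.82, adjusted p = 3.4e-28), with Acat2 at −1.18 ± 0.11, as were 6 of 9 other SREBP-2 targets (8 adjusted over the list alone, adjusted p = 1.9e-07) and 7 of 19 genes of fatty acid synthesis (13 adjusted over the list alone, adjusted p = 9e-10). Of 18 LXR targets 4 were lower (1 up and 6 down adjusted over the list alone, adjusted p = 0.00764). Of 14 stress genes 4 were higher (10 up and 1 down adjusted over the list alone, adjusted p = 0.000123, and 0.0801 with an estimated correlation), and Aldh1l2 was higher by 2.32 ± 0.32. In sum 170 genes were higher and 265 lower. The total of 435 was 237 without DMHCA replicate 1, 779 without DMHCA replicate 2, 177 without MePipHCA replicate 1 and 210 without MePipHCA replicate 2.

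Against T0901317 in hepatocytes Abca1 was lower with DMHCA by −2.49 ± 0.09, Abcg1 by −3.38 ± 0.58, Srebf1 by −1.14 ± 0.10, Scd1 by −2.39 ± 0.08 and Fasn by −0.78 ± 0.08. Of 19 genes of fatty acid synthesis 9 were lower (12 adjusted over the list alone, adjusted p = 5.4e-19) and of 18 LXR targets 6 (1 up and 6 down adjusted over the list alone, adjusted p = 1.1e-06). With MePipHCA Abca1 was lower by −3.19 ± 0.10, Abcg1 by −4.91 ± 0.67, Srebf1 by −1.48 ± 0.10, Scd1 by −2.63 ± 0.08 and Fasn by −1.11 ± 0.08, and 18 of 20 cholesterol biosynthesis enzymes were lower, also adjusted over the list alone (adjusted p = 7.6e-23). Calls were 58 higher and 72 lower for DMHCA, 130 in sum and 59 without T0901317 replicate 1. For MePipHCA they were 414 higher and 383 lower, 797 in sum, and 298 without MePipHCA replicate 1, 316 without MePipHCA replicate 2, 482 without T0901317 replicate 1 and 367 without T0901317 replicate 2. Against desmosterol at 10 uM, Hmox1 was higher with DMHCA at 1 uM (0.73 ± 0.08), while Abca1 (95% interval −0.49 to −0.12, adjusted p = 0.273) and Scd1 (95% interval −0.11 to 0.19) did not differ past the threshold. Fasn was higher (0.36 ± 0.08, adjusted p = 0.045), a call lost without DMHCA replicate 1 (0.31, adjusted p = 0.281) or desmosterol replicate 1 (0.38, 0.246) or 2 (0.34, 0.272), with adjusted p values of 0.000122 to 0.296 over all settings. Of 20 cholesterol biosynthesis enzymes 2 were higher (11 adjusted over the list alone, median 0.23, adjusted p = 1.8e-09). This comparison had 17 genes higher and 23 lower, 40 in sum, and 3 without DMHCA replicate 1, 132 without DMHCA replicate 2, 17 without desmosterol replicate 1 and 18 without desmosterol replicate 2.

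**Figure D2:**
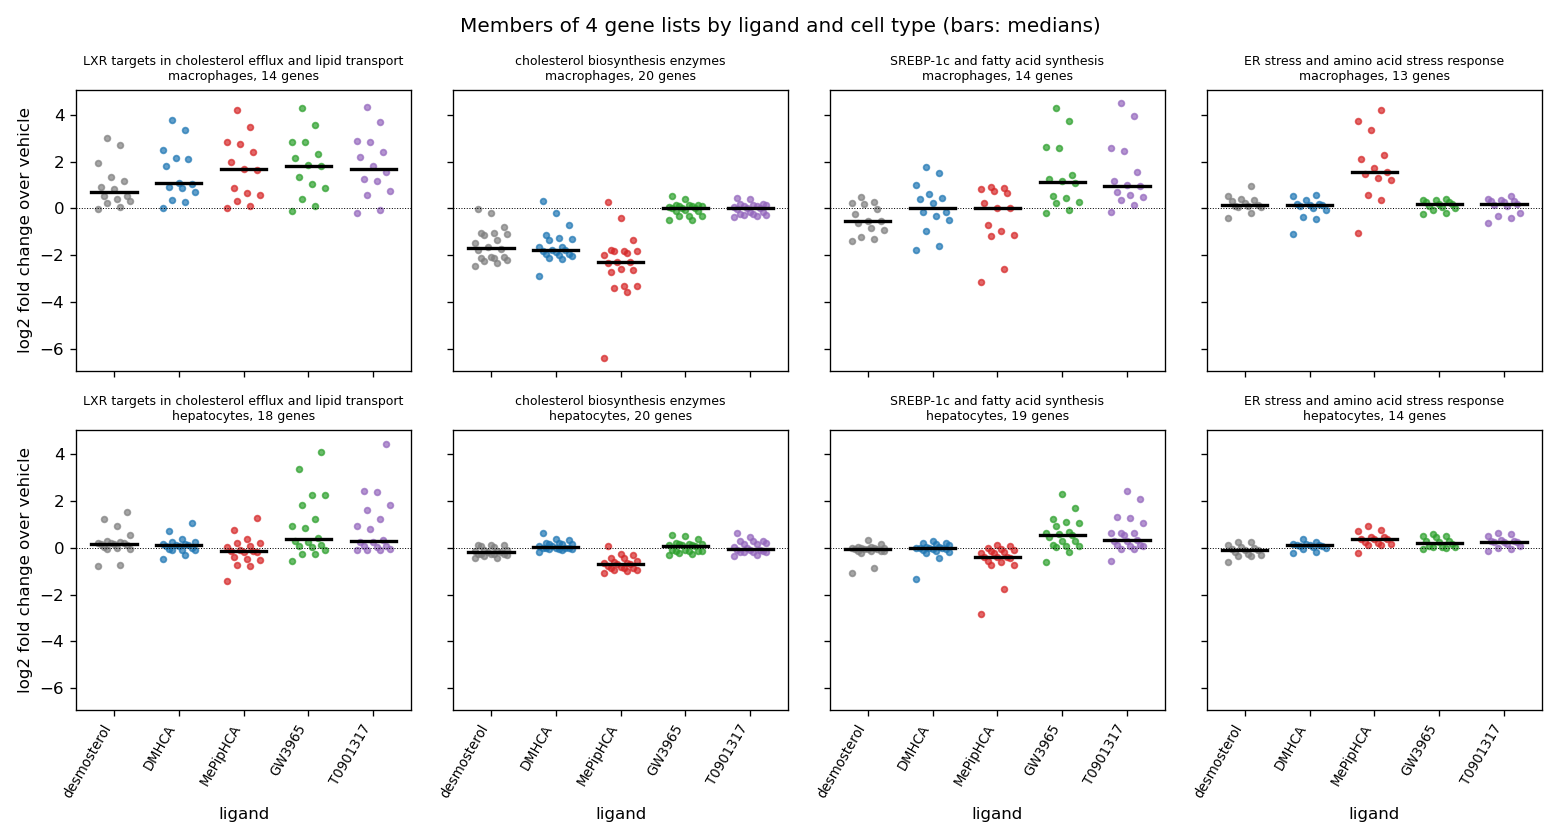
Log2 fold change over vehicle of each tested member of the lists of LXR targets, cholesterol biosynthesis enzymes, SREBP-1c and fatty acid synthesis, and stress genes, by ligand, in macrophages and hepatocytes. Dots are genes and bars are medians, the lowest being −2.29 for cholesterol biosynthesis enzymes with MePipHCA in macrophages.

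The interaction of ligand and cell type asks whether the change over vehicle differed between macrophages and hepatocytes. All values are macrophage minus hepatocyte. For desmosterol the log2 difference was 2.79 ± 0.10 for Abca1, −0.91 ± 0.13 for Scd1 and −1.16 ± 0.11 for Fasn. For DMHCA it was 3.84 ± 0.11 for Abca1, 1.38 ± 0.12 for Srebf1 and 0.94 ± 0.12 for Scd1. For MePipHCA it was 4.99 ± 0.11 for Abca1, 1.11 ± 0.12 for Srebf1 and 1.06 ± 0.12 for Scd1, while Fasn did not differ (0.03 ± 0.11). The stress genes Chac1 (3.80 ± 0.32), Asns (3.02 ± 0.19) and Trib3 (2.96 ± 0.20) rose more in macrophages with MePipHCA. With GW3965 and T0901317 Abca1 differed by 2.04 ± 0.10 and 1.94 ± 0.10, Srebf1 by 1.35 ± 0.12 and 1.34 ± 0.12, Scd1 by 1.96 ± 0.11 and 2.10 ± 0.11 and Fasn by 1.48 ± 0.11 and 1.38 ± 0.11.

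By list, the change over vehicle was lower in macrophages for 18 of 20 cholesterol biosynthesis enzymes with desmosterol, DMHCA and MePipHCA. With MePipHCA 1 was higher. Camera adjusted p values were 1.8e-47, 5.8e-51 and 5.8e-28, with 18 lower adjusted over the list alone with each. In this paragraph higher and lower refer to the change over vehicle, not to levels. GW3965 and T0901317 gave 1 higher and 1 lower (adjusted p = 0.622 and 0.957). Of 18 LXR targets 5, 8 and 10 were higher with desmosterol, DMHCA and MePipHCA (7, 12 and 13 adjusted over the list alone, adjusted p = 8.1e-07, 5.6e-23 and 8.1e-20), and 8 were higher and 1 lower with each synthetic agonist (adjusted p = 1.3e-08 and 2.9e-06). Changes of fatty acid synthesis genes were higher in macrophages for 7 of 19 with GW3965 and 6 with T0901317. Adjusted over the list alone, 9 were up with GW3965, and 7 up and 1 down with T0901317 (camera adjusted p = 1.1e-08 and 4.9e-07). With desmosterol 1 was higher and 6 lower (2 and 7 adjusted over the list alone, adjusted p = 0.0033, and 0.0736 with an estimated correlation). Stress genes were higher for 10 of 14 with MePipHCA (10 up and 1 down adjusted over the list alone, median 1.39, adjusted p = 4.1e-15) and for 4 with desmosterol (7 up and 1 down adjusted over the list alone, adjusted p = 0.00119). Markers of stellate cells and fibroblasts had 2 of 8 lower with MePipHCA (adjusted p = 6.4e-05), and none of 3 B cell markers differed with any ligand. Calls numbered 346, 377, 1324, 426 and 498 for desmosterol, DMHCA, MePipHCA, GW3965 and T0901317. Without hepatocyte vehicle replicate 1 they were 207, 202, 994, 260 and 331, and those for DMHCA also moved to 246 without macrophage vehicle replicate 2 and to 648 without hepatocyte DMHCA replicate 2.

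Some calls of a difference between the cell types were lost without 1 library, while the difference itself stayed nearly as large. Abcg1 and Mylip were scarce in hepatocytes, so the size of their differences is poorly measured. With desmosterol the Mylip difference exceeded the macrophage change of 2.73, so part of it comes from the hepatocyte estimate, where Mylip was not called. Mylip differed by 3.53 ± 0.62 with desmosterol and 3.47 ± 0.59 with DMHCA, where without hepatocyte vehicle replicate 1 it was 3.28 (adjusted p = 0.116) and 3.21 (adjusted p = 0.125) and the adjusted p was, over all settings, 3.9e-07 and 6.3e-09 at the lowest. It differed by 3.40 ± 0.58 with MePipHCA. With T0901317 it differed by 2.17 ± 0.52 (1.92, adjusted p = 0.343, without hepatocyte vehicle replicate 1, and an adjusted p of 0.000156 at the lowest), and with GW3965 by 1.77 ± 0.50 (adjusted p = 0.0366), a call lost without macrophage GW3965 replicate 3 (1.74, adjusted p = 0.0504), hepatocyte GW3965 replicate 2 (1.64, 0.101), hepatocyte vehicle replicate 1 (1.52, 0.515) or hepatocyte vehicle replicate 2 (1.88, 0.0846), with an adjusted p of 0.00231 at the lowest. Abcg1 differed by 3.27 ± 0.82 with MePipHCA, with 3.23 and an adjusted p of 0.184 without hepatocyte vehicle replicate 1, and an adjusted p of 0.00116 at the lowest. Fasn differed by −0.48 ± 0.11 with DMHCA (adjusted p = 0.00876), a call lost without macrophage DMHCA replicate 2 (−0.40, adjusted p = 0.0617), macrophage vehicle replicate 2 (−0.40, 0.0627), hepatocyte DMHCA replicate 1 (−0.42, 0.0603) or hepatocyte vehicle replicate 2 (−0.41, 0.0675), with an adjusted p of 0.000531 at the lowest.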

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

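The tests of macrophage RNA in a hepatocyte library, of Gpnmb, of stromal cells, of counts in sum and of the macrophage share were chosen only after the result was seen. Each result given first is a difference between the cell types in the response to a ligand, macrophage minus hepatocyte, that passed the interaction test. By this test the 2 cell types differed in 346 genes with desmosterol, 377 with DMHCA, 1324 with MePipHCA, 426 with GW3965 and 498 with T0901317. Without hepatocyte vehicle replicate 1 these counts were 207, 202, 994, 260 and 331, of which 167, 176, 884, 217 and 267 were the same genes, and the count for DMHCA was 246 without macrophage vehicle replicate 2 and 648 without hepatocyte DMHCA replicate 2. Cell type, medium and date go together in this design, so that they cannot be told apart.

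Among the genes followed throughout, the log2 difference with desmosterol was 2.79 for Abca1, 3.53 for Mylip, 0.42 for Srebf1, −0.91 for Scd1 and −1.16 for Fasn. With DMHCA it was 3.84 for Abca1, 3.47 for Mylip, 1.38 for Srebf1, 0.94 for Scd1 and −0.48 for Fasn. With MePipHCA it was 4.99 for Abca1, 3.27 for Abcg1, 3.40 for Mylip, 1.11 for Srebf1, 1.06 for Scd1, 3.80 for Chac1, 3.02 for Asns and 2.96 for Trib3. With GW3965 it was 2.04 for Abca1, 1.77 for Mylip, 1.35 for Srebf1, 1.96 for Scd1 and 1.48 for Fasn. With T0901317 it was 1.94 for Abca1, −1.56 for Abcg1, 2.17 for Mylip, 1.34 for Srebf1, 2.10 for Scd1 and 1.38 for Fasn. Abcg1 and Mylip were scarce in hepatocytes, so the size of their differences is poorly measured. Srebf1 with desmosterol (adjusted p = 0.0477) was past the threshold neither without macrophage desmosterol replicate 1 (adjusted p = 0.0519), 2 (0.129) or 3 (0.0571) nor without macrophage vehicle replicate 1 (0.152) or 3 (0.0842), hepatocyte desmosterol replicate 1 (0.241) or hepatocyte vehicle replicate 1 (0.382), where its differences were 0.30 to 0.45, with an adjusted p of 0.0188 at the lowest over all settings. Abcg1 with T0901317 (adjusted p = 0.0405) lost its call without macrophage T0901317 replicate 1 (adjusted p = 0.0532) or 3 (0.0593), macrophage vehicle replicate 2 (0.0555) or 3 (0.0533), hepatocyte T0901317 replicate 1 (0.109), hepatocyte vehicle replicate 1 (0.35) or 2 (0.142), where its differences were −1.41 to −1.60, with an adjusted p of 0.0307 at the lowest. Without hepatocyte vehicle replicate 1 Mylip lost its call with desmosterol (3.28, adjusted p = 0.116), DMHCA (3.21, adjusted p = 0.125), GW3965 (1.52, adjusted p = 0.515) and T0901317 (1.92, adjusted p = 0.343), and Abcg1 with MePipHCA (3.23, adjusted p = 0.184), so that these differences stayed nearly as large while their calls ended with 1 vehicle library left.

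No test linked the first pattern weighed to those lost calls. Hepatocyte vehicle replicate 1 held more of the transcripts that abound in macrophages than other hepatocyte libraries did. Of 53 genes above 500 CPM in macrophages and scarce in hepatocytes 48 lay above the median of the other hepatocyte libraries. The median share was 0.0909% of the macrophage level (quartiles 0.0659 to 0.149), whereas the medians of the other libraries ranged from −0.0114 to 0.0244. By the same measure 40 of 54 genes lay above in GW3965 replicate 1 and 33 of 54 in GW3965 replicate 2. Macrophage RNA or reads in this library are a candidate source, since Gpnmb stood at 32.3 CPM against a mean of 33550 in macrophages, Lyz2 at 16.3 and Ctss at 12.1. A lowering of Gpnmb by the ligands in hepatocytes was argued against by vehicle replicate 2, which at 1.96 CPM lay within the 0.459 to 3.52 of the ligand-treated libraries. Whether the transcripts entered as cells, RNA or reads stays open, and resident macrophages of the liver were not separated from these.

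The second pattern is the lower level of fibroblast matrix genes and of contractile genes in macrophage cultures with MePipHCA. The 4 matrix genes fell by a like amount (weighted mean −1.40 ± 0.07, p of a difference between them 0.353). Fewer stromal cells in these cultures could give such a fall, while a lowered transcription in such cells was not tested. The pooled SEs and the p-values of a difference between genes take genes of the same libraries as independent. They may therefore be too small or too large. The 2 contractile genes fell by more and not alike (−4.30 ± 0.32 and −2.91 ± 0.30, p of a difference between them 0.00155), with a pooled difference from the matrix genes of −2.15 ± 0.23 that leaves out their spread. The smaller of these falls still lay beyond the largest of a matrix gene (−1.55), so that fewer stromal cells alone leave part of their fall open. All 4 matrix genes still fell with every library thinned to 1 depth, with a median of −1.403 against −1.409 at full depth. Thinning leaves a scaled level the same on average, so this outcome was fixed in advance and decides nothing about depth.

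The third pattern is the larger number of changed genes, and the rise of amino acid stress genes, with MePipHCA than with DMHCA in macrophages. Depth was argued against as the cause, since the MePipHCA libraries held 0.905 times the counts of the DMHCA libraries in sum (15.69 M and 17.33 M). At 1 depth in every library MePipHCA called 3.26 times as many genes as DMHCA (3204 and 982) against 3.03 times before, which decides nothing further, as the depths differed the other way. A gain in the macrophage share through loss of other cells was weighed by 7 abundant macrophage markers. With MePipHCA over DMHCA their largest change was −0.039 ± 0.053 (Cd68), below the smallest rise of 0.43 ± 0.05 among the 11 stress genes that were higher. With MePipHCA over vehicle it was −0.109 ± 0.053, below the smallest rise of 0.37 among 12 stress genes. Markers of this list also fell with GW3965 and T0901317, so a lowering by ligands could hide a gain in share. The markers therefore cannot decide this. The stress genes that rose did so unequally. Over DMHCA their median rise was 1.82 and the smallest 0.43 ± 0.05, and over vehicle 1.63 and 0.37 ± 0.07. A gain in share alone would raise genes expressed mainly in macrophages by a like factor. The unequal rises argue against it as the sole source for the stress genes, and do not bear on the number of changed genes. A difference between the compounds at 1 uM stays open as an untested biological explanation, as does any difference in handling between the groups that the labels do not give.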

How the results depend on the processing

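Leaving out the libraries that stood apart was chosen only after seeing the data, and the other tests were planned. No call of a gene described in the report reversed. Over named genes that were called, leaving out 1 library kept the call in 2853 of 3192 cases in macrophages, 707 of 1144 in hepatocytes and 1095 of 1220 for the difference between cell types, and DESeq2 kept 478 of 527, 232 of 241 and 119 of 121. RLE size factors moved no count of genes by over 1.5 times. With an estimated correlation 22 of 72 lists called by camera in macrophages, 22 of 46 in hepatocytes and 4 of 22 for the difference lost their call. Fry, which sets no list against other genes, called 24, 3 and 10 lists that camera did not and lost 3, 10 and 2. Counts of genes moved as follows. DESeq2 gave, in hepatocytes, 93 genes with desmosterol, 98 with GW3965, 251 with T0901317 and 202 for DMHCA against T0901317. Without the filter on low counts, with 17946 genes tested, hepatocytes gave 139 genes with desmosterol, 22 with DMHCA, 163 with GW3965, 256 with T0901317, 271 for DMHCA against T0901317 and 122 for DMHCA against desmosterol. Fits of only the groups compared, which leave fewer libraries for the spread, gave 173 genes for DMHCA against desmosterol in macrophages, and in hepatocytes 490 with MePipHCA, 107 with GW3965, 63 for DMHCA against T0901317 and 12 for DMHCA against desmosterol. The replicate number as a block gave 1 gene with DMHCA in hepatocytes. In camera this block ended 6 of 72 list calls in macrophages, 2 of 46 in hepatocytes and 0 of 22 for the difference. It added 0, 1 and 2 list calls. Without the libraries standing apart hepatocytes gave 4 genes with DMHCA, 74 with T0901317, 349 for MePipHCA against T0901317 and 14 for DMHCA against desmosterol. The causes of these changes were not tested.

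Leaving out 1 library at a time gave, in macrophages, 665 to 1042 genes with desmosterol, 898 to 1205 with DMHCA, 336 to 495 for DMHCA against T0901317 and 158 to 300 for DMHCA against desmosterol. In hepatocytes it gave 15 to 41 with desmosterol, 0 to 27 with DMHCA, 114 to 207 with MePipHCA, 28 to 54 with GW3965, 48 to 107 with T0901317, 177 to 779 for MePipHCA against DMHCA, 59 to 168 for DMHCA against T0901317, 298 to 482 for MePipHCA against T0901317 and 3 to 132 for DMHCA against desmosterol. For the difference between cell types it gave 207 to 302 with desmosterol, 202 to 648 with DMHCA, 260 to 384 with GW3965 and 331 to 483 with T0901317. For 62 results of named genes DESeq2 gave no adjusted p, 42 were not tested in fits of only the groups compared and 3 not without the libraries standing apart. Hepatocyte groups with 1 library left relied on the spread of the other groups, and 64.2% of genes changed 2-fold in simulated counts were called in hepatocytes as for the difference between cell types, with depth not separated from replicate number or spread.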

Other observations

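The tests of other splits of the libraries were planned, and the other values here were looked at after seeing the data. For each macrophage comparison the 6 libraries can be split in 10 ways, so the share of splits with as many genes cannot go under 0.1, and in each comparison 1 split, the real one, gave its count. Each split was fitted on these 6 libraries alone, so its counts differ from those of the fit of all groups. The real split called 775 genes with desmosterol, 1585 with DMHCA, 4534 with MePipHCA, 1684 with GW3965, 1442 with T0901317, 2927 for MePipHCA against DMHCA, 563 for DMHCA against T0901317, 2863 for MePipHCA against T0901317 and 173 for DMHCA against desmosterol, and the highest of the other splits called 0 in each. Every other split mixes libraries of both groups, so a real difference widens its spread and lowers its calls. These counts of 0 therefore do not measure how many calls unrelated libraries would give.

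Libraries stood apart within some groups. The first principal component held 44.9% of the variance in macrophages and 14.5% in hepatocytes. In macrophages it lay mainly between groups, with the MePipHCA libraries at −35.97, −33.24 and −32.17 and all others at −8.64 to 16.37. In hepatocytes T0901317 replicate 2 lay at 34.62 and replicate 1 at 2.04. Replicates of a group differed by a chi-square per degree of freedom of 1.39 to 7.77 in macrophages, the highest in pairs with desmosterol replicate 2, and of 5.66 to 13.24 in hepatocytes, the highest between the DMHCA replicates, so that no pair was a duplicate. Hepatocyte vehicle replicate 2 had the fewest counts of its cell type (6.63 M) and the lowest share of reads in exons (77.98%). The 10 most abundant genes took 17.39 to 19.07% of counts in macrophages and 7.19 to 8.36% in hepatocytes. Of the 346, 377, 1324, 426 and 498 genes that differed between cell types with desmosterol, DMHCA, MePipHCA, GW3965 and T0901317, 303, 343, 1216, 373 and 447 had at least 1 CPM in both. Those with the largest differences were mostly scarce in hepatocytes: of the 16, 16, 16, 19 and 20 genes picked for size, in the same order, 14, 12, 13, 16 and 17 had a mean below 1 CPM in hepatocytes, and 4, 6, 3, 6 and 4 changed sign without hepatocyte vehicle replicate 1. They are for that reason not described gene by gene.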
